A study of Arabidopsis thaliana with 8 samples.

How the data were processed

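Total RNA from whole light-grown Arabidopsis thaliana seedlings of the Columbia (Col) background, 5 days old, was measured on 8 single-colour Affymetrix arrays, 1 per sample. The groups were wild type (2 arrays), the aha1 mutant (3 arrays, 2 of allele aha1-6 and 1 of allele aha1-7) and the aha2 mutant (3 arrays, 2 of allele aha2-4 and 1 of allele aha2-5). AHA1 and AHA2 are plasma membrane proton pumps, which move protons out of the cell at the expense of ATP. A string shared by the sample descriptions splits the arrays into a first set of 3 (1 array per group) and a second set of 5 (1 wild type, 2 aha1, 2 aha2), and every group had arrays in both. Nothing in the labels says that the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Replicate numbers only name samples: replicate 1 of each group lies in the first set, and replicate 3 of each mutant is the second allele.

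The deposited values are linear intensity values per probe set, made with Affymetrix Expression Console 1.1 per the submitters' processing notes, and the summarisation algorithm is not given in the sources used here. The 2% trimmed mean of every array lay at 1000.1, while array medians ran from 358.1 to 410.2 and between 18.4% and 23.7% of probe sets per array had a signal under 50. The table held 22810 probe sets, of which 64 were array controls. No 2 arrays shared more than 0.00438% identical signals.

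Because the medians differed, the values were taken as log2(value + 1) and quantile normalized over all probe sets, controls included. The controls were then left out, and 22746 probe sets were tested. Fold changes are therefore on the log2(value + 1) scale after normalization. A linear model with group and set as terms was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom), and p-values were adjusted with the Benjamini-Hochberg method over all tested probe sets at a threshold of 0.05. The set was planned as a block and was kept. Deviations from the group means, taken over all arrays, were compared for pairs of arrays without aha1-7. Their median correlation was 0.338 for arrays of the same set and different groups (lowest -0.0014, highest 0.465). With set as a random block, the estimated correlation within a set was 0.031 over all tested probe sets. The number of arrays limits the precision.

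Probe sets were named from the platform annotation used here, with symbols updated through the gene identifiers of the RefSeq table of assembly TAIR10.1. It gave 1 gene for 13513 probe sets, several genes for 503 and no gene for 8730 of those tested. Probe sets with several genes or none were tested but are given no gene name. For genes with more than 1 probe set, the one with the highest mean over all arrays was used. AHA1, AHA2 and the other plasma membrane proton pump genes have no named probe set in that annotation, so the targeted genes were not checked by name and the labels are taken as given.

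The tests, the gene lists and the rule for naming genes were chosen before the data were examined. The rule took, for each mutant against wild type, single-gene probe sets past the threshold with every mutant array on the same side of the wild type array of its set, up to 12 in each direction. Where fewer than 10 passed, the direction was filled up to 10 with the largest fold changes at an unadjusted p under 0.01, given as values that did not pass. For aha1 against aha2 it took 5 in each direction, and for each list up to 4 members with the smallest p. Genes outside it are said to have been chosen after their values were seen. Gene lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives, and adjusted over the lists tested together. Of 479 genes on the 22 fixed lists, 69 had a named probe set, and 10 lists could be tested. A further 15 lists were added after the annotation had been seen, 1 of them (glucosinolate genes) after 2 genes of that pathway had been seen, and were adjusted among themselves.

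On simulated data with the real means and spreads and 100 changed probe sets of each size, the fit over all 22746 probe sets recovered 0% of changes of 1 and 20% of changes of 2 on the log2 scale for aha1 against wild type, 0% and 17% for aha2 against wild type, and 2% and 42% for aha1 against aha2. Over the 11373 brighter probe sets those shares were 45% and 100%, 31% and 99%, and 58% and 100%. False calls numbered 0, 3 and 2 over all probe sets in the same order of comparisons, and 5, 6 and 11 over the brighter ones. The simulation gave every array the same spread at a probe set, aha1-7 included, and no difference between the sets. The shares may therefore overstate the recovery in the real data. There the brighter probe set 266939_at, at a log2 fold change of -3.28 in aha1 against wild type, did not pass (limma, adjusted p = 0.873 over the brighter probe sets). The alternatives were no set term, set as a random block, subsets of arrays, each array left out, other normalizations, dim probe sets left out, multi-gene probe sets left out, other variance models and thresholds, and another log offset. Alternatives chosen after seeing the data were the deposited scaling alone, the brighter probe sets without the aha1-7 array, and named probe sets with each array's trend over gene length removed by a lowess smoother (span 0.3).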

Results

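Transcript levels were measured on single-colour oligonucleotide arrays in 5-day-old light-grown Arabidopsis seedlings of wild type (2 arrays) and of plants carrying mutations in either of a pair of plasma membrane proton pump genes, AHA1 (3 arrays) and AHA2 (3 arrays). Each mutant was represented by a pair of alleles, aha1-6 and aha1-7 or aha2-4 and aha2-5, with 1 array for each second allele. Values are normalized log2 intensities, with SD over arrays, unless given as signal in the deposited linear units. Array medians ran from 358.1 to 410.2 signal units. The targeted genes have no named probe set in the annotation used here, and the genotypes are those of the labels.

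The aha1-7 array stood apart from the others. Over the 11373 brighter probe sets its median correlation with the other arrays was 0.887, against 0.959 to 0.971 for the remaining 7. It differed by more than 2-fold from the mean of the others at 1201 of these probe sets (927 lower, 274 higher), where no other array exceeded 56. On this array, short genes were low and long genes were high: among 5883 named genes the median deviation from the other arrays was -0.86 in the shortest 10% and 0.52 in the longest 10%. Gene length here is the span from gene start to gene end in the RefSeq table, introns included, and transcript length was not used. Across genes, which are not independent replicates, Spearman's rho between deviation and gene length was 0.69 for this array and between -0.30 and 0.28 for the others, each against a mean without aha1-7. Values of aha1 are therefore also given without this array where that changes them.

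**Figure D1:**
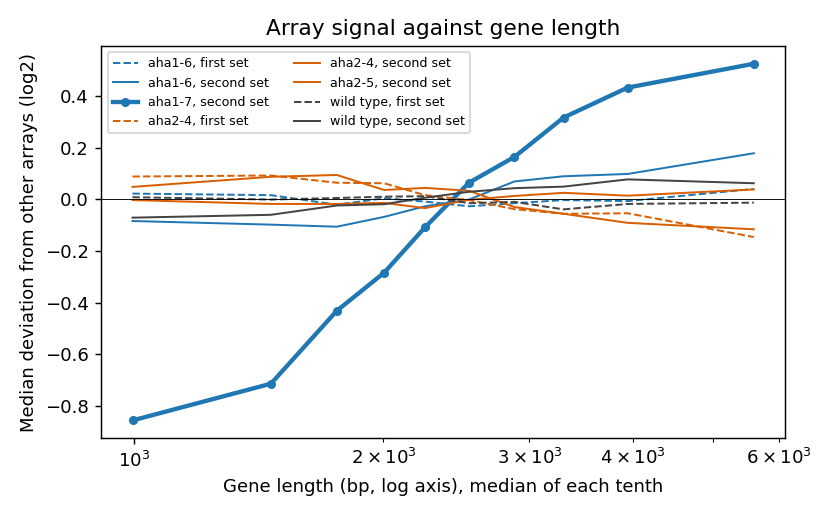
Median deviation of each array from the mean of the other arrays without aha1-7 (log2, vertical axis) for groups of equal number among 5883 named, brighter genes ordered by gene length (base pairs, log axis). The thick line with points is the aha1-7 array, which runs from -0.86 at the shortest genes to 0.52 at the longest; dashed lines are arrays of the first set and solid lines those of the second.

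The comparison of aha2 with wild type asked which transcripts depend on the AHA2 pump. Of 22 genes of the iron deficiency response, fixed as a list in advance, only 5 had a named probe set. These were higher in aha2: all 5 measured members had a positive fitted fold change, with a median of 0.84 on the log2 scale (camera, adjusted p = 1.21e-05, or 0.0776 with an estimated correlation). On each single aha2 array, 4 members were above the wild type array of the set and 1 was below. BHLH101, a transcription factor of the iron deficiency response, was at 9.23 ± 0.19 (SD, n = 3) in aha2 and 6.94 ± 0.39 (SD, n = 2) in wild type, a 5.09-fold difference (log2 fold change 2.35, SE 0.33). AT3G13610, known as F6'H1 and required for the synthesis of coumarins that mobilise iron, was at 11.91 ± 0.03 (SD, n = 3) in aha2 and 10.44 ± 0.05 (SD, n = 2) in wild type, a 2.75-fold difference. Over all probe sets neither of these genes passed (limma, adjusted p = 0.374 and 0.329), while both passed when adjusted over the list alone, 2 of 5 members against 0 over all genes tested. A further list of iron deficiency genes, added later, had a median of 0.44 over 15 measured members (camera, adjusted p = 0.000433; adjusted p = 0.252 with an estimated correlation). Its median was 0.13 and the call was lost without wild type replicate 1 (camera, adjusted p = 0.0948). Against the wild type array of the set, the median of this further list was 0.51 and 0.60 on the aha2-4 arrays. On the aha2-5 array it was 0, with 8 members higher and 7 lower.

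PYK10, an abundant root beta-glucosidase and the only measured member of the root marker list, was at 14.85 ± 0.16 (SD, n = 3) in aha2 and 14.98 ± 0.07 (SD, n = 2) in wild type. A later list of 13 root-abundant class III peroxidases was higher in aha2, with a median of 0.38 (camera, adjusted p = 0.000167; adjusted p = 0.782 with an estimated correlation). The 4 measured shoot photosynthesis markers had a median of 0.09 (camera, adjusted p = 0.618), and the 2 measured root hair genes were too few for a list test. The 4 measured flavonoid and anthocyanin genes were higher in aha2, with a median of 0.57 (camera, adjusted p = 0.0137; adjusted p = 0.442 with an estimated correlation). Among them DFR, which makes the precursors of anthocyanins, was at 8.70 ± 0.40 (SD, n = 3) against 7.99 ± 0.26 (SD, n = 2). The flavonoid call was lost without aha2 replicate 1 (adjusted p = 0.171), aha2 replicate 2 (adjusted p = 0.0866), wild type replicate 1 (adjusted p = 0.0677) or wild type replicate 2 (adjusted p = 0.128).

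Chloroplast-encoded transcripts, a list added later, were lower in aha2, with a median of -0.39 over 69 genes, 63 of them negative (camera, adjusted p = 1.02e-11; adjusted p = 0.313 with an estimated correlation). The difference from the wild type array of the same set was -0.32, -0.51 and -0.25 in the 3 aha2 arrays, and 0.03, -0.21 and 0.30 in the 3 aha1 arrays. rpoC1, a subunit of the plastid RNA polymerase, was at 7.96 ± 0.23 (SD, n = 3) in aha2 and 9.17 ± 0.71 (SD, n = 2) in wild type. The 21 nuclear photosynthesis genes of a further list had a median of 0.00 (camera, adjusted p = 0.965).

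**Figure D2:**
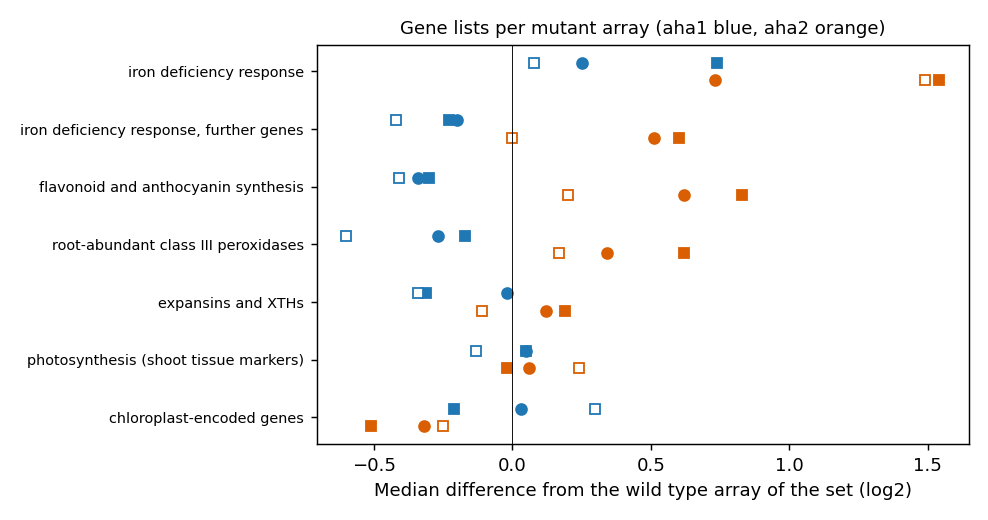
Median difference of each mutant array from the wild type array of its own set (log2, horizontal axis) for 7 gene lists; blue is aha1, orange aha2, circles the first set, squares the second, and open symbols the aha1-7 and aha2-5 alleles. The iron deficiency list lies between 0.73 and 1.54 in the aha2 arrays and between 0.08 and 0.74 in the aha1 arrays.

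Over single probe sets, 0 of 22746 passed in aha2 against wild type with limma, and 919 had an unadjusted p under 0.05, where chance alone gives 1137. With the dimmest 50% left out, 3 of 11373 probe sets passed, all higher in aha2: AT3G13610, AT5G38900 and the unnamed probe set 267565_at. AT5G38900 was at 9.62 ± 0.09 (SD, n = 3) in aha2 and 8.25 ± 0.26 (SD, n = 2) in wild type, a 2.64-fold difference (limma, adjusted p = 0.0482). The probe set 267565_at had a log2 fold change of 2.28 (SE 0.25), at 10.57 ± 0.67 (SD, n = 3) in aha2 and 8.53 ± 1.55 (SD, n = 2) in wild type. Its wild type arrays lay far apart, at 9.63 in the first set and 7.44 in the second, and the small SE rests on the set term. When the aha1-7 array, which adds to the shared estimate of the spread, was also left out, 61 passed (48 higher, 13 lower in aha2). Among the 31 named ones were AT1G47400 of the further iron list (log2 fold change 1.53, SE 0.19), AT1G26380 (1.91, SE 0.27), AT2G43590 (1.24, SE 0.14) and the plastid genes psaA (-1.58, SE 0.29), rpoC1 (-1.09, SE 0.19), ycf3 (-1.08, SE 0.18), rpl33 and psbB. These genes were chosen after their values were seen.

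The genes the naming rule took for aha2 did not pass, and all 20 lay below the median signal. The 10 highest had log2 fold changes from 2.77 to 3.66: AT1G12030, YUC11, AT1G52800, AT2G31100, AT2G28490, AT1G41797, AT1G34545, AT3G03430, SK19 and AT1G33580. YUC11 encodes a flavin monooxygenase of auxin synthesis. The 10 lowest had values from -3.57 to -2.67: QQS, AT3G04390, AT1G04625, AT1G31540, AT3G56520, AT2G19360, AT1G61750, AGL99, AT3G32080 and AT5G56770. Apart from QQS, the lower group's mean signal at these genes was between 0.436 and 15.6, near the bottom of the range. With 16 in place of 1 added before the logarithm the values ran from 0.72 to 2.69 and from -1.75 to -1.12, so their sizes rest on that offset and are not measured folds.

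The comparison of aha1 with wild type asked the same of the AHA1 pump. Cell wall loosening genes, the fixed list of expansins and xyloglucan endotransglucosylase/hydrolases (XTHs), were lower in aha1, with a median of -0.29 and 11 of 15 measured members negative (camera, adjusted p = 0.0367; adjusted p = 0.523 with an estimated correlation). EXPB3 was at 10.92 ± 0.07 (SD, n = 3) in aha1 and 11.35 ± 0.12 (SD, n = 2) in wild type, and XTH19 at 8.89 ± 0.41 (SD, n = 3) against 9.66 ± 0.22 (SD, n = 2). The larger lists of these families, added later, were not called: 18 expansins with expansin-like genes had a median of -0.22 (adjusted p = 0.063), and 24 XTHs with family GH9 glucanases had 0.05, with 13 positive (adjusted p = 0.719). Without the aha1-7 array the median was -0.21 and the call was lost (adjusted p = 0.188), as it was with the gene length trend removed (adjusted p = 0.18), without aha1 replicate 2 (adjusted p = 0.169), without wild type replicate 2 (adjusted p = 0.244) and without aha2 replicate 1 (adjusted p = 0.0694). The root-abundant peroxidases had a median of -0.32 in aha1 (camera, adjusted p = 0.0149; adjusted p = 0.675 with an estimated correlation), and -0.28 without the aha1-7 array (adjusted p = 0.105).

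The methionine chain elongation gene BCAT4, which acts in aliphatic glucosinolate synthesis, was lower in every aha1 array. Its signal was 2051 ± 375 (SD, n = 3) in aha1, 3920 ± 196 (SD, n = 3) in aha2 and 5356 ± 293 (SD, n = 2) in wild type, a 2.62-fold difference between aha1 and wild type (log2 fold change -1.39; limma, adjusted p = 0.389 over all probe sets and 0.12 over the brighter ones). COR15A, a cold-regulated chloroplast protein, was at 3.59 ± 0.20 (SD, n = 3) in aha1 and 6.02 ± 0.62 (SD, n = 2) in wild type, near the bottom of the signal range, and was the 1 member of the 5 measured abscisic acid, cold and drought genes to pass when adjusted over the list alone (0 over all genes tested). BCAT4 was chosen after its values were seen.

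Over single probe sets, 0 of 22746 passed in aha1 against wild type with limma, and 1139 had an unadjusted p under 0.05, where chance alone gives 1137. With the dimmest 50% left out the count was also 0, with 580 at an unadjusted p under 0.05. When the aha1-7 array was left out as well, which leaves aha1-6 alone, 27 passed (17 higher, 10 lower). The 7 named ones were BCAT4 (log2 fold change -1.28, SE 0.15) and AT3G28220 (-1.69, SE 0.26), both lower, and AT5G57760 (1.47, SE 0.15), AT5G62280 (1.42, SE 0.24), AT2G39400, AT2G41730 and AT5G43450, all higher. The aha1-7 array lay on the same side of its wild type array at 24 of the 27, while at AT5G57760 it differed from wild type by -0.27. Apart from BCAT4 these genes too were chosen after their values were seen.

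The naming rule took 20 genes for aha1, none past the threshold and all below the median signal. The 10 highest had log2 fold changes from 2.83 (AT4G40020) to 4.203 (AT2G33350): AT2G33350, AT5G27480, AT1G35820, AT2G06500, AT3G62180, AT1G33880, AT2G14825, AGL29, AT5G34920 and AT4G40020. The 10 lowest had values from -3.78 to -2.74: QQS, AT5G44980, AT2G31700, AT5G17950, AT5G56880, AGL99, OCT1, AT3G46270, AT4G08060 and AOP3, the last another gene of glucosinolate synthesis. Here too, apart from QQS, the lower group's mean signal was only between 1.58 and 16.9, and with 16 added the values ran from 1.36 to 2.19 and from -2.34 to -0.95, so the sizes are not measured folds.

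QQS, a gene known from Arabidopsis alone that acts on starch content, had the lowest fold change of the genes the naming rule took in either mutant. Its signal was 136 ± 69.9 (SD, n = 3) in aha1 and 140 ± 71.2 (SD, n = 3) in aha2, against 1677 ± 201 (SD, n = 2) in wild type (limma, adjusted p = 0.491 and 0.558). AT1G34545, chosen for aha1 after its values were seen, had a signal of 8.11 ± 0.99 (SD, n = 2) in wild type, 58.5 ± 2.26 (SD, n = 3) in aha1 and 73.7 ± 27.8 (SD, n = 3) in aha2 (limma, adjusted p = 0.226 and 0.175). Across all 22746 probe sets the aha1 and aha2 effects had a Pearson correlation of 0.46 and a covariance of 0.145. Unchanged groups simulated against the same wild type arrays gave 0.60 and a covariance of 0.145. With a different wild type array for each mutant, the correlation was -0.01 both ways. Over the 11373 brighter probe sets the correlation was -0.03 with the shared wild type arrays, against 0.60 in the simulation, and -0.05 and -0.18 with different wild type arrays. The simulation gave every array the same spread at a probe set. Among the brighter ones, the aha1-7 array was more than 2-fold from the mean of the others at 1201, against 24 and 19 for the wild type arrays. The simulated value follows from the design and may be no fair reference there.

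**Figure D3:**
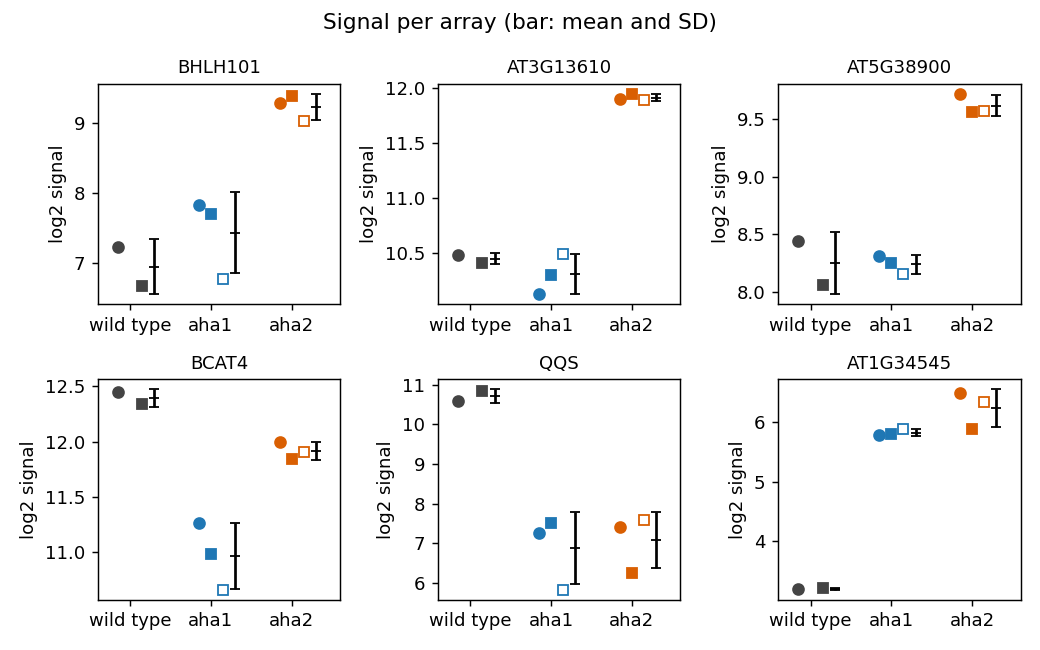
Normalized log2 signal of 6 genes on each array (vertical axis), by group; circles are the first set, squares the second, open symbols the aha1-7 and aha2-5 alleles, and bars the mean and SD of the group. BHLH101, AT3G13610 and AT5G38900 are higher in the 3 aha2 arrays, BCAT4 is lowest in the 3 aha1 arrays, and QQS and AT1G34545 separate both wild type arrays from the 6 mutant arrays.

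The direct comparison of the mutants gave the most differences. The iron deficiency genes were lower in aha1 than in aha2 (median -0.68, 4 of 5 negative; camera, adjusted p = 0.00139), as were the expansins and XTHs (median -0.34, 15 of 15 negative; adjusted p = 0.000622) and the flavonoid genes (median -0.89, 4 of 4 negative; adjusted p = 0.00139). With an estimated correlation the adjusted p was 0.212 for each of the 3 lists, and without the aha1-7 array the iron median was -0.45 (camera, adjusted p = 0.00087). Of the further lists, chloroplast-encoded genes were higher in aha1 (median 0.41; adjusted p = 2.05e-08), while root-abundant peroxidases (-0.77; adjusted p = 1.71e-07), further iron genes (-0.58; adjusted p = 1.26e-05), tau-class glutathione S-transferases (-0.60; adjusted p = 0.00154), expansins with expansin-like genes (-0.34; adjusted p = 0.00514) and ATG8 autophagy genes (-0.42; adjusted p = 0.00514) were lower. None of the 6 held with an estimated correlation, where the smallest adjusted p was 0.136. Without the aha1-7 array the chloroplast-encoded, peroxidase and iron lists were called, and the calls ended for the glutathione S-transferases (median -0.41; adjusted p = 0.0864), the expansins with expansin-like genes (-0.20; adjusted p = 0.0758) and ATG8 (-0.06; adjusted p = 0.281). The ATG8 median against the wild type array of the set was -0.95 on the aha1-7 array and -0.04 and -0.05 on the aha1-6 arrays.

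Over single probe sets, 0 of 22746 passed in aha1 against aha2 with limma, and 2417 had an unadjusted p under 0.05, where chance alone gives 1137. With the dimmest 50% left out, 20 passed, 17 of them lower in aha1. The 7 named ones were AT5G38910 (log2 fold change -2.46, SE 0.23), AT2G43590 (-2.11, SE 0.29), AT3G54040, AT3G13610, AT5G38900 and AT4G15390, all lower in aha1, and AT2G30600 (1.24, SE 0.18), higher in aha1. When the aha1-7 array was left out too, 344 passed (154 higher, 190 lower in aha1), of which 165 were named. Against 344 of all 11373, they held 4 of the 10 brighter root-abundant peroxidases, 4 of the 8 further iron genes, 4 of the 23 UDP-glycosyltransferases, 1 of the 3 fixed-list iron genes and 1 of the 9 tau-class glutathione S-transferases, all lower in aha1, and 6 of the 51 chloroplast-encoded genes, all higher. Under the naming rule the largest values, none past the threshold, were for AT4G04300, AT5G27480, AT4G16010, AT5G34920 and AT1G31540, from 3.01 to 3.70, and for AT3G46270, AT1G80970, AT5G39880, AT5G44980 and AT5G17950, from -3.44 to -2.90. The lower group's mean signal at these 10 was between 0.861 and 17.1, and with 16 added the values ran from 1.18 to 1.64 and from -2.23 to -1.09.

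The remaining fixed lists with a test were not called in either mutant against wild type. The 7 measured vacuolar proton pump genes had medians of 0.06 in aha1 and 0.05 in aha2, and the 4 measured genes that regulate the plasma membrane pump had 0.33 and 0.03. The 7 auxin response genes were at -0.01 and 0.08, the 5 abscisic acid, cold and drought genes at -0.08 and 0.08, the 4 touch and rapid stress genes at 0.28 and 0.26, and the 4 heat shock genes at -0.28 and -0.31. In aha1 the iron deficiency genes had a median of 0.12 (camera, adjusted p = 0.967), the flavonoid genes -0.29 (adjusted p = 0.117) and the shoot photosynthesis markers -0.07 (adjusted p = 0.967), and in aha2 the expansins and XTHs had 0.04 (adjusted p = 0.295). In aha1, mean and median differed in sign for the vacuolar pump genes (mean -0.02) and the auxin genes (mean 0.05), and the test of the heat shock genes pointed upward (camera, adjusted p = 0.967) against a mean of -0.25.

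Alleles of one gene could be compared only as values. In the second set the difference from wild type correlated across the brighter probe sets with r = 0.28 between aha1-6 and aha1-7 and with r = 0.53 between aha2-4 and aha2-5, each pair sharing 1 wild type array. With different wild type arrays r was 0.05 between the aha1 alleles and 0.27 between the aha2 alleles, and 0.40 and 0.29 between the arrays of aha1-6 and of aha2-4. Over all probe sets these 4 values were 0.00, 0.06, 0.05 and 0.05, and those with the shared wild type array 0.42 for aha1 and 0.53 for aha2.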

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

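The tests of gene length, RNA quality, allele and root share in this part were chosen after the results were seen, while the splits of the samples were planned before their counts were seen. The effects of the mutants differed, by the direct test of aha1 against aha2, for 3 fixed lists: iron deficiency genes (camera, adjusted p = 0.00139), expansins and XTHs (adjusted p = 0.000622) and flavonoid genes (adjusted p = 0.00139). With an estimated correlation the adjusted p was 0.212 for each of the 3, and none was called. The same test over the brighter probe sets gave a difference for 7 named genes, with log2 fold changes of -2.46 for AT5G38910, -1.76 for AT3G54040, -1.61 for AT3G13610, -1.38 for AT5G38900, -2.11 for AT2G43590, -1.09 for AT4G15390 and 1.24 for AT2G30600. The 6 mutant arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2417 probe sets at an unadjusted p under 0.05 and the highest other 2107, and only 1 split of the 10, the real one itself, reached that count. Over the brighter probe sets the real split gave 20 calls and the highest other 0, so that again only 1 split, the real one, reached the count.

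The first pattern is the separate position of the aha1-7 array. A high 3' to 5' ratio of the control transcripts, read as degraded RNA, is argued against for these transcripts alone. The mean log2 ratio of actin, GAPDH and ubiquitin was 1.47 on this array, below the 1.60 to 2.14 of the others. Actin was lowest on it (3.21), while GAPDH (-0.49) and ubiquitin (1.71) lay within the range of the other arrays. The ratio was thus not raised, and other kinds of RNA quality loss were not tested. A bias by gene length has the values it needs, since rho with length was 0.69 and removing the trend took away 56.1% of the named genes that differed by more than 2-fold from the other arrays. Of 702 such genes 308 were left, but rho with length was still 0.26 after the removal. The genes left may therefore still reflect length, and whether length is the whole cause stays open. An effect of the allele cannot be told apart from a length bias, because only 1 array carries the allele.

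The second pattern is the higher level of iron deficiency genes in aha2. A larger share of root tissue stays open for the 5 fixed-list genes. Their median exceeded that of the root-abundant peroxidases by 0.88 on average over the 3 aha2 arrays (SE 0.27, lowest 0.39). In aha1, where the iron list was not called, it did so too, with mean levels of 0.36 for the iron genes and -0.35 for the peroxidases. An excess found in both mutants cannot decide the cause of a rise in aha2. For the 15 further iron deficiency genes the same difference was -0.01 (SE 0.10) in aha2. Mean levels were 0.37 for these genes and 0.38 for the peroxidases, as a larger root share would need. The other organ markers did not move with the peroxidases. PYK10, the only measured root marker, had a log2 fold change of -0.13 in aha2 against wild type. Medians were 0.09 for the 4 shoot photosynthesis markers and -0.004 for the 21 further nuclear photosynthesis genes. A larger root share therefore stays open for the further iron genes, on the peroxidases alone. The aha2 arrays of the second set share a wild type array, so neither SE rests on independent values. Gene length bias is argued against for the fixed list, since its median was 0.81 with the length trend removed (camera, adjusted p = 8.33e-06) and 0.84 before. Loss of AHA2 itself, the difference the design names, stays open as a hypothesis and was not tested apart from other differences between the lines.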

How the results depend on the processing

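The alternatives with the deposited scaling, named probe sets, gene length, the brighter probe sets without aha1-7, and all those for the further lists and for lists of aha1 against aha2 were chosen after seeing the data. The planned checks of AHA1 and AHA2 were not run, because no probe set is named for them here, and the first set alone gave no test. For aha1 against wild type the count of 0 probe sets moved only to 27, with the dimmest 50% and aha1-7 left out. For aha2 against wild type it became 1 with the dimmest 25% left out, 3 with 50% left out, 2 with trend and robust eBayes, and 61 with 50% and aha1-7 left out. For aha1 against aha2 those counts were 10, 20, 19 and 344, with 14 for eBayes with trend and 14 at an adjusted p threshold of 0.1. With each array left out in turn all 3 counts were 0, and with no replicate block all 3 counts were 0.

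The count of called fixed lists for aha1 against wild type, 1, became 0 with an estimated correlation, fry, named probe sets alone or the length trend removed, 2 with the dimmest 50% left out, and 0 to 1 with single arrays left out. For aha2 against wild type, 2 became 0 with an estimated correlation, 1 with fry, 1 with the dimmest 50% left out, and 1 to 2 with single arrays left out. For aha1 against aha2, 3 became 0 with an estimated correlation and 3 to 4 with single arrays left out. Among the further lists, the 1 call for aha1 became 0 with an estimated correlation, fry or the length trend removed, 3 with no replicate block, 6 and 3 with the dimmest 25% and 50% left out, 4 with the deposited scaling, and 0 to 4 with single arrays left out. The 3 calls for aha2 became 0 with an estimated correlation or fry and 5 with either dim filter, and 2 to 3 with single arrays left out. The 6 calls between the mutants became 0 with an estimated correlation, 1 with fry, 3 without the aha1-7 array and 3 to 7 over all single arrays left out.

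The correlation of the effects, 0.46, was 0.60 in the simulation and -0.01 with different wild type arrays in either order. With the dimmest 50% left out, chosen after seeing the data, it was -0.03, with 0.60 in the simulation and -0.05 and -0.18 with different wild type arrays. The simulation took the same spread on every array, aha1-7 included, so its value may be no fair reference. PYK10 in aha1, at 0.02, was -0.03 without wild type replicate 2 and with array weights, -0.05 without the aha1-7 array with or without the dim filter (-0.05 to 0.19 with single arrays left out), and -0.06 with the length trend removed. Of 2032 alternative values of single genes, 1943 kept direction and side of the threshold, 84 passed it and 5 changed sign. No probe set passed in the main fit, so keeping the side only means staying short of the threshold, and no gene could lose a call. Genes taken for large fold changes also had little room to change sign, so these counts are no measure of how firm the gene results are. Of 286 alternative values for lists, 46 lost the call. Dim probe sets limit the fit, as the simulated recovery shows. Fewer probe sets were tested with dim ones left out, and how far that or a changed spread raised the counts was not tested. The cause of the other changes was not tested either.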

Other observations

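The test of pairs of arrays in this part was planned before its counts were seen, and no other test of an explanation is given here. The genes named here were chosen after their values were seen. In aha2, SWEET14, a sugar transporter of the SWEET family, was at 8.39 ± 0.17 (SD, n = 3) against 7.24 ± 0.00 (SD, n = 2) in wild type, and was the 1 of 14 measured SWEET genes to pass when adjusted over the list alone. BGLU43 was at 3.64 ± 0.64 (SD, n = 3) in aha2 and 5.82 ± 0.20 (SD, n = 2) in wild type, near the bottom of the signal range. It was the 1 of 21 beta-glucosidase genes to pass over its list alone. Over all probe sets neither passed (limma, adjusted p = 0.503 and 0.575). The glucosinolate list, written after BCAT4 and AOP3 had been seen and without them, had a median of -0.20 in aha1 (camera, adjusted p = 0.119) and -0.14 in aha2 (adjusted p = 0.802). The further lists for mitochondrion-encoded genes, UDP-glycosyltransferases, XTHs with family GH9 glucanases, RALF-like peptides and the TBL wall acetylation family, were called in none of the 3 comparisons.

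Among the brightest 10% of probe sets, the lowest against wild type in both aha1 alleles was 266939_at, which the annotation used here does not name. Its signal was 3800 and 4629 on the aha1-6 arrays and 60.5 on the aha1-7 array, against 11280 ± 407 (SD, n = 2) in wild type and 12010 ± 1402 (SD, n = 3) in aha2. The lowest in aha2-4, also unnamed, was 253609_at, at 831 and 932 on the aha2-4 arrays, and at 11870 on the aha2-5 array, against 16840 ± 2327 (SD, n = 2) in wild type and 15480 ± 4219 (SD, n = 3) in aha1. With a wide spread between the alleles of a mutant, neither passed in the grouped test (limma, adjusted p = 0.937 for 266939_at in aha1 and 0.9998 for 253609_at in aha2). Over the brighter probe sets without the aha1-7 array 266939_at did pass, at a log2 fold change of -1.41 (SE 0.15) in aha1 against wild type (adjusted p = 0.00209) and -1.41 against aha2 (adjusted p = 0.000451), where the fold change with all arrays was -3.28 against wild type. The lowest in aha2-5 was another unnamed probe set, 248377_at, at a log2 difference of -1.62, which was second lowest in aha2-4, at -1.29. It did not pass in aha2 (adjusted p = 0.621), but did over the brighter probe sets without the aha1-7 array, at a log2 fold change of -1.38 (SE 0.15, adjusted p = 0.00189). No gene is known here for any of these probe sets, so whether they measure the targeted genes, and bear on the labels of the arrays, stays open. AT1G05910 had a signal of 16.9 on the aha1-7 array and between 447.5 and 876.5 on the other 7.

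The third pattern is the separation of both wild type arrays from all mutant arrays at QQS and AT1G34545. At 26 probe sets, 16 higher and 10 lower in the mutants, both wild type arrays lay outside the range of the 6 mutant arrays by more than that range. Of the 28 pairs of arrays, 23 gave as many such probe sets, the highest other pair gave 231 and the median of the other pairs was 37, so chance cannot be excluded for the set of 26. The highest other pair was aha1 replicate 2 with the aha1-7 array, both of the aha1 group and the second set. A shared effect of pump loss, or a difference between the wild type and mutant seed lines, may lie behind single genes such as QQS; neither was tested.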
